A study of Mus musculus with 9 samples.

How the data were processed

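Total RNA of mouse intestine was sequenced in 9 libraries, 3 of each group: control given corn oil, IR given corn oil and 12 Gy of whole abdominal irradiation on day 4, and IR+LYC given lycopene by gavage at 10 mg/kg per day for 10 days with the same irradiation on day 4. A group given lycopene alone was not analysed here. Per the submitters' processing notes, reads were trimmed with fastp (version not given in the sources used here) and aligned with HISAT2 2.0.5. The deposited table holds FPKM values, which are not log2 values, for 54532 Ensembl genes. Its genome build is not given in the sources used here; 54495 of the IDs are in GENCODE M21 (GRCm38), 53585 of them with the same chromosome, start and end, and coordinates are printed on that build.

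Reads were recovered from the FPKM of each library as whole numbers per gene length, and 202261 of 202261 values (100%) were whole within 0.01 read. The recovered totals were 20107262, 18259881 and 18008213 reads in control, 19792860, 18763261 and 18941912 in IR, and 22414949, 17834561 and 17803889 in IR+LYC. The divisor in the deposited values was 0.854 to 1.26 times these totals, so the authors had scaled each library by a further factor. A single read on 1 kb corresponded to 0.0354 to 0.0656 FPKM. Mitochondrially encoded genes took 3.16 to 4.84% of the reads.

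Gene differences were tested on log2(FPKM + 1), computed here, with limma 3.58.1 in R 4.3.3, as moderated contrasts with a mean-variance trend in 1 model of the 3 groups, with 6 residual and 8.18 total degrees of freedom. Genes with at least 0.5 FPKM in at least 3 libraries entered, 15391 in all, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Of 42 gene lists of cell types and pathways, 37 with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with the correlation estimated and with fry. A preset correlation makes small p-values easier to reach when members move together, so the adjusted p with an estimated correlation is given beside each call. The 5 lists with fewer members were left out. Members of each list were also adjusted over that list alone.

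Genes are named by a rule: up to 8 symbols per direction past the threshold whose groups did not overlap and whose higher group had a mean of at least 5 FPKM, predicted genes left out, up to 4 members of a list with the smallest p, 5 genes per direction where none passed, and 16 fixed genes. Some genes named in the text fall outside this rule and are said to. The groups, comparisons, lists, fixed genes and most alternatives were chosen before the data were examined, and some alternatives were added after the data had been seen. Alternatives changed the pseudocount to 0.1, removed the filter or required a mean of 5 FPKM, and rescaled by median ratios or without mitochondrial, immunoglobulin and pancreatic genes. Others fitted only the 2 groups compared, dropped the trend, added a block for the replicate number, used limma-voom on recovered reads (16806 genes with 10 reads), required a log2 difference of 1, or left out each library in turn. Positions between control and IR were computed on genes selected in fits of the controls with the other 2 IR libraries, so that no IR library helped choose the axis on which it was placed.

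The procedure was tested on simulated data with each gene's own spread. In IR against control 49.3% of 2-fold, 68.7% of 4-fold and 93.9% of 8-fold changes were recovered, with 9 calls on unchanged genes. The same shares were 44.8, 73.1 and 93.9% in IR+LYC against IR, with 7, and 41.8, 64.2 and 92.4% in IR+LYC against control, with 14. A shifted list was called in each of the 3 comparisons, and 0 of 33 other lists were. The simulation held no variation shared between genes, which the real libraries have. Changes were placed only in genes above a minimum mean of reads. The shares may thus be too high for the real data, and few calls there do not show that large changes are absent. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.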

Results

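The series asks whether lycopene lessens injury of the mouse intestine by abdominal irradiation, and 3 groups of 3 libraries were compared: control, irradiated (IR) and irradiated with lycopene (IR+LYC). Between 17803889 and 22414949 reads per library were recovered from the FPKM values, and 15391 genes were tested. The labels do not say that the libraries are separate animals, so the p-values measure the spread between samples. The gut segment is not given in the labels either.

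The libraries of the IR+LYC group differed from one another more than those of the other groups. Spearman correlations within groups ran from 0.874 (IR+LYC 1 with IR+LYC 2) to 0.981 (control 2 with control 3). The first principal component held 61.2% of the variance. On it the controls lay at -44.0, -22.9 and -30.7, the IR libraries at 1.45, 44.3 and -8.50, and the IR+LYC libraries at 66.6, -41.4 and 35.1. IR+LYC 2 thus lay on the control side of that component, and it stood apart on the second (10.3%), at 35.1 against -21.5 to 4.87 for the others. The brush border enterocyte genes moved with this. Their score was 0.997 in IR+LYC 2 against -2.78 and -1.08 in the other 2 IR+LYC libraries. It was -1.67 in IR 2 against 0.528 and 0.649 in IR 1 and IR 3. The ileal bile acid binding protein gene Fabp6 (chromosome 11, 43596049 to 43601540) was at 0.593, 89.9 and 253 FPKM in the controls, 305.3, 1561 and 119 in IR, and 93.9, 0.274 and 419 in IR+LYC. The tissue taken may therefore not have been of 1 segment throughout.

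**Figure D1:**
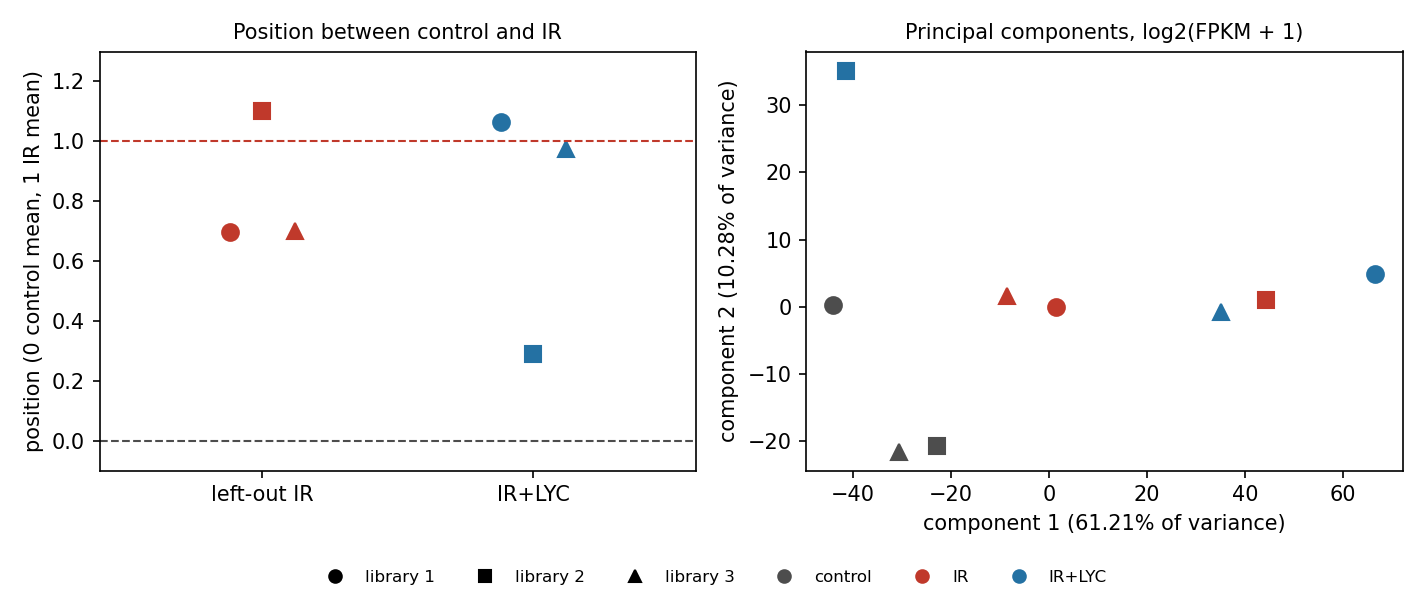
Left, position of each irradiated library between the control mean (0) and the IR mean (1), for IR libraries left out of the axis and for IR+LYC libraries. Right, the 9 libraries on the first 2 principal components.

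In IR against control the lymphocyte and plasma cell lists were lower with a preset correlation between members, and neither passed with an estimated one (adjusted p = 0.426 for both). Over all genes tested, 0 of their members passed. Igkv3-4, a kappa light chain variable segment, fell from 25.2 ± 5.59 to 3.21 ± 0.876 FPKM (SD, n = 3), and it was lower in 3 of 3 IR libraries than in every control. Ccl5, a chemokine of activated T cells and natural killer cells, was at 105.0 ± 30.3 FPKM in control and 10.5 ± 2.75 in IR, without passing the test gene by gene. Paneth, tuft and enterocyte lists were lower, and smooth muscle, matrix and macrophage lists higher, with the preset correlation alone. With an estimated correlation their adjusted p was 0.578, 0.426, 0.692, 0.578, 0.578 and 0.578, and the enterocyte call ended without IR 2 (0.1004).

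The 3 genes that passed in IR against control were all lower. Igkv3-4 (ENSMUSG00000096715, chromosome 6, 70671788 to 70672377) fell by 2.63 on the log2 scale (standard error 0.21, limma adjusted p = 0.0199), with 181, 178 and 109 reads in the controls and 29, 19 and 21 in IR. Igkv3-9 (ENSMUSG00000095338, chromosome 6, 70588189 to 70588777), another kappa segment, had 38, 19 and 26 reads in the controls and 0, 0 and 2 in IR (log2 -2.30, adjusted p = 0.0199, lower in 3 of 3). Reads of such segments can be shared between paralogs, so which segment was lost is uncertain. Mir7061 (ENSMUSG00000104914, chromosome 7, 130908268 to 130908335), a microRNA precursor, had 1 read in each control and 0 elsewhere (adjusted p = 0.0239), which is too little to describe its level. Igkv3-9 and Mir7061 fall outside the rule for naming genes and were named after their values were seen. Over the alternatives the adjusted p ran from 0.0118 to 0.105 for Igkv3-4, 0.0145 to 0.194 for Igkv3-9 and 0.000117 to 0.264 for Mir7061. The count of 3 became 0 without control 1, IR 1, IR 2, IR 3 or IR+LYC 1, 1 without control 2 or control 3, 4 without IR+LYC 3 and 98 without IR+LYC 2. With limma 1284 genes had an unadjusted p under 0.05 (601 higher, 683 lower); limma-voom passed 0 genes, with 1344 unadjusted. The 2 groups did not overlap at 4319 genes, 28.1% where the 10 splits of the 6 libraries average about 10%. Genes move together, so any 1 split can lie far from that average, and no excess over chance is shown.

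T and intraepithelial lymphocyte genes were lower as a set (17 of 19 members, median log2 -0.86, camera adjusted p = 4.35e-11; adjusted p = 0.426 with an estimated correlation). Of these, 9 passed when adjusted over the list alone and 0 over all genes tested. Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) differed by -3.20 log2 (adjusted p = 0.265, lower in 3 of 3). Trdc, the constant region of the delta T cell receptor, was at 2.85 ± 0.267 FPKM in control and 0.663 ± 0.252 in IR. Cd160, a receptor of cytotoxic lymphocytes, was at 3.66 ± 1.09 and 1.28 ± 0.248. Itgae, the integrin that holds intraepithelial lymphocytes to the epithelium, was at 10.6 ± 2.79 and 4.35 ± 0.301. B and plasma cell genes were lower in 18 of 18 members (median log2 -1.33, adjusted p = 2.10e-09; adjusted p = 0.426 with an estimated correlation). Of these, 8 were past the threshold adjusted over the list alone and 0 over all genes tested. Igha, the heavy chain of immunoglobulin A, was at 3604 ± 780.2 FPKM in control and 647 ± 323 in IR, and Jchain, which joins its units, at 747 ± 223 and 141 ± 64.2. Derl3, of protein folding in plasma cells, was at 6.86 ± 1.04 and 1.80 ± 0.661. Immunoglobulin genes took 1.496 to 2.01% of the recovered reads of the controls and 0.205 to 0.488% in IR.

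Some epithelial lists were lower, while goblet cell genes (median log2 0.12, adjusted p = 0.638) and enteroendocrine genes (median log2 -0.10, adjusted p = 0.182) did not pass. Paneth cell genes were lower in 14 of 16 members (median log2 -0.96, adjusted p = 9.20e-08; adjusted p = 0.578 with an estimated correlation). Adjusted over the list alone 4 passed, and 0 over all genes tested. Defa26 and Defa5, antimicrobial defensins whose paralogs share reads and are therefore uncertain, were at 241 ± 15.8 and 181 ± 17.4 FPKM in control and 112 ± 38.9 and 71.7 ± 23.1 in IR. Tuft cell genes were lower in 8 of 10 members (median log2 -0.45, adjusted p = 3.67e-05; adjusted p = 0.426 with an estimated correlation). Adjusted over the list alone 6 passed, and 0 over all. Rgs13, a regulator of G protein signalling, was at 3.59 ± 0.676 and 0.798 ± 0.299 FPKM, and Avil, an actin binding protein, at 1.99 ± 0.295 and 0.776 ± 0.130. Pou2f3, the transcription factor that tuft cells need, was at 0.668 ± 0.0608 and 0.233 ± 0.114. Xenobiotic metabolism genes were lower in 22 of 23 members (median log2 -0.90, -0.52 without IR 2, adjusted p = 4.85e-06; adjusted p = 0.578 with an estimated correlation, with 0 members past either threshold). The cytochrome Cyp2c55 was at 18.1 ± 8.24 and 2.45 ± 0.353 FPKM. Enterocyte brush border genes were lower in 20 of 20 members (median log2 -1.16, -0.45 without IR 2, adjusted p = 0.000258; adjusted p = 0.692 with an estimated correlation, with 0 members past either threshold). The call was lost without IR 2 (adjusted p = 0.1004). The glucose transporter genes Slc5a1 and Slc2a2 were at 949 ± 238 and 67.5 ± 28.3 FPKM in control and 316 ± 209 and 16.7 ± 14.7 in IR. Bco1 (ENSMUSG00000031845, chromosome 8, 117095854 to 117133720), the oxygenase that cleaves carotenes to retinal, was at 16.4 ± 3.06 FPKM in control and 1.22 ± 0.365 in IR (log2 -2.97, standard error 0.83, adjusted p = 0.397, lower in 3 of 3). In the fit of these 2 groups alone its adjusted p was 0.00769, within a range of 0.00769 to 0.878 over the alternatives.

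Muscle, matrix and myeloid genes were higher. Smooth muscle genes were higher in 12 of 12 members (median log2 1.03, adjusted p = 9.73e-07; adjusted p = 0.578 with an estimated correlation, with 0 members past either threshold). The actin Actg2 (chromosome 6, 83512905 to 83536265) was at 124 ± 15.3 FPKM in control and 439 ± 73.3 in IR, and desmin (Des) at 59.7 ± 7.91 and 149 ± 19.7. Extracellular matrix genes were higher in 19 of 20 members (median log2 0.66, adjusted p = 1.81e-07; adjusted p = 0.578 with an estimated correlation; 1 past the threshold adjusted over the list alone, 0 over all). That member was Loxl2, which crosslinks collagen, at 2.89 ± 0.427 and 6.90 ± 0.900 FPKM (log2 1.02, adjusted p = 0.142). Macrophage and monocyte genes were higher in 12 of 16 members (median log2 0.58, 0.37 without IR 2, adjusted p = 1.55e-05; adjusted p = 0.578 with an estimated correlation, with 0 members past either threshold). Cd68, a lysosomal protein of macrophages, was at 8.59 ± 0.645 and 18.1 ± 4.66 FPKM. Neutrophil genes were higher in 4 of 6 members (median log2 0.57, adjusted p = 0.0159; adjusted p = 0.426 with an estimated correlation). Adjusted over the list alone 2 passed, and 0 over all genes tested. S100a8, a subunit of calprotectin, was at 0.0820 ± 0.0819 and 1.16 ± 0.122 FPKM. Its control level is near that of single reads, so the size of the difference is uncertain.

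Among 23 targets of p53, 3 passed adjusted over the list alone and 0 over all genes tested. Eda2r (ENSMUSG00000034457, chromosome X, 97333840 to 97377216), a receptor of the cell surface, was at 0.218 ± 0.0268 FPKM in control and 1.39 ± 0.296 in IR (log2 0.96, adjusted p = 0.200, higher in 3 of 3). Phlda3 (ENSMUSG00000041801, chromosome 1, 135766119 to 135769136), an inhibitor of AKT, was at 4.28 ± 0.441 and 14.8 ± 2.74 (log2 1.57, adjusted p = 0.361), and cyclin G1 (Ccng1) at 24.9 ± 0.832 and 39.5 ± 1.61 (log2 0.64, adjusted p = 0.284). Of the 23 targets 15 were higher (median log2 0.10, 0.15 without control 3, adjusted p = 0.00724; adjusted p = 0.426 with an estimated correlation). The set call ended with genes at a mean of at least 5 FPKM (median -0.15, adjusted p = 0.756). In the fit of the 2 groups alone the adjusted p was 0.0306 for Eda2r, 0.0209 for Phlda3 and 0.0449 for Ccng1. Over the alternatives Eda2r ran from 0.0300 to 0.587 and Phlda3 from 0.0169 to 0.867. Cell cycle genes were higher in 23 of 24 members (median log2 0.30, 0.16 without IR 2, adjusted p = 9.32e-06; adjusted p = 0.692 with an estimated correlation, with 0 members past either threshold). Aurka, a mitotic kinase, was at 10.1 ± 1.70 and 14.5 ± 4.19 FPKM. Regenerative epithelium genes were higher in 14 of 18 members (median log2 0.54, 0.29 without IR 2, adjusted p = 0.00274; adjusted p = 0.578 with an estimated correlation, with 0 members past either threshold). The set did not pass without IR 2 (adjusted p = 0.0545) or at a mean of at least 5 FPKM (0.117). Anxa3, an annexin of that state, was at 2.59 ± 0.183 and 5.93 ± 2.63 FPKM. Interferon response genes were higher in 22 of 24 members (median log2 0.54, 1.12 without IR 1 and -0.01 without IR 2, adjusted p = 0.00274; adjusted p = 0.692 with an estimated correlation, with 0 members past either threshold), but without IR 2 the call ended (adjusted p = 0.700). Their scores in IR 1, IR 2 and IR 3 were -0.712, 1.37 and 0.614, and the chemokine Cxcl9 was at 5.13, 29.0 and 22.6 FPKM in these libraries.

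Of the 16 genes fixed in advance for the question of injury and protection, 15 were tested and none passed in any comparison in the fit of all 9 libraries. Without IR+LYC 2, Bco1 passed in IR against control (adjusted p = 0.00949), among 98 of 15391 genes (0.637%). In that fit 4120 of 15391 genes (26.8%) passed in IR+LYC against control, so fixed genes would pass often whatever their role. Of the 15, 7 did: Olfm4 (log2 0.99, adjusted p = 0.0174), Cdkn1a (-1.10, 0.0206), Hmox1 (0.94, 0.0235), Bax (0.76, 0.0292), Tjp1 (-0.52, 0.0373), Alpi (-2.74, 0.0467) and Bco1 (-3.25, 0.00789). In IR+LYC against control these values are the lowest over the alternatives, and the highest were 0.743 for Olfm4, 0.772 for Cdkn1a, 0.710 for Hmox1, 0.695 for Bax, 0.706 for Tjp1, 0.868 for Alpi and 0.706 for Bco1. The stem cell gene Lgr5 was at 1.62 ± 0.113 FPKM in control, 1.27 ± 0.160 in IR and 1.29 ± 0.682 in IR+LYC. Olfm4, of the crypt base, was at 278 ± 22.5, 312 ± 22.9 and 455 ± 168, and the proliferation marker Mki67 at 18.1 ± 2.28, 20.1 ± 1.90 and 20.7 ± 2.57. Cdkn1a, the cell cycle inhibitor p21, was at 70.8 ± 5.88, 54.9 ± 11.8 and 49.2 ± 29.1, Bax at 23.6 ± 3.99, 32.8 ± 5.24 and 35.8 ± 7.50, and its opponent Bcl2 at 1.56 ± 0.162, 1.62 ± 0.215 and 1.85 ± 0.198. Lysozyme of Paneth cells (Lyz1) was at 8696 ± 871, 4704 ± 1294 and 6106 ± 2525, the goblet cell mucin Muc2 at 24.5 ± 6.12, 22.6 ± 2.89 and 38.3 ± 6.81, and intestinal alkaline phosphatase (Alpi) at 267 ± 37.4, 159.8 ± 100.1 and 169 ± 206. The carotenoid transporter Scarb1 was at 2.12 ± 0.0295, 2.27 ± 0.352 and 2.56 ± 0.229. The antioxidant enzymes Nqo1 and Hmox1 were at 19.1 ± 3.04 and 2.07 ± 0.0221 in control, 21.1 ± 1.72 and 4.56 ± 1.22 in IR, and 20.2 ± 3.95 and 4.02 ± 1.71 in IR+LYC. The cytokine Tnf was at 0.5001 ± 0.106, 0.965 ± 0.404 and 0.936 ± 0.775, and Tjp1, of tight junctions, at 17.7 ± 1.46, 16.1 ± 2.54 and 13.4 ± 2.41. Il6 stayed below the filter, at 0.0404 ± 0.0148, 0.0206 ± 0.00211 and 0.0133 ± 0.0231 FPKM.

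**Figure D2:**
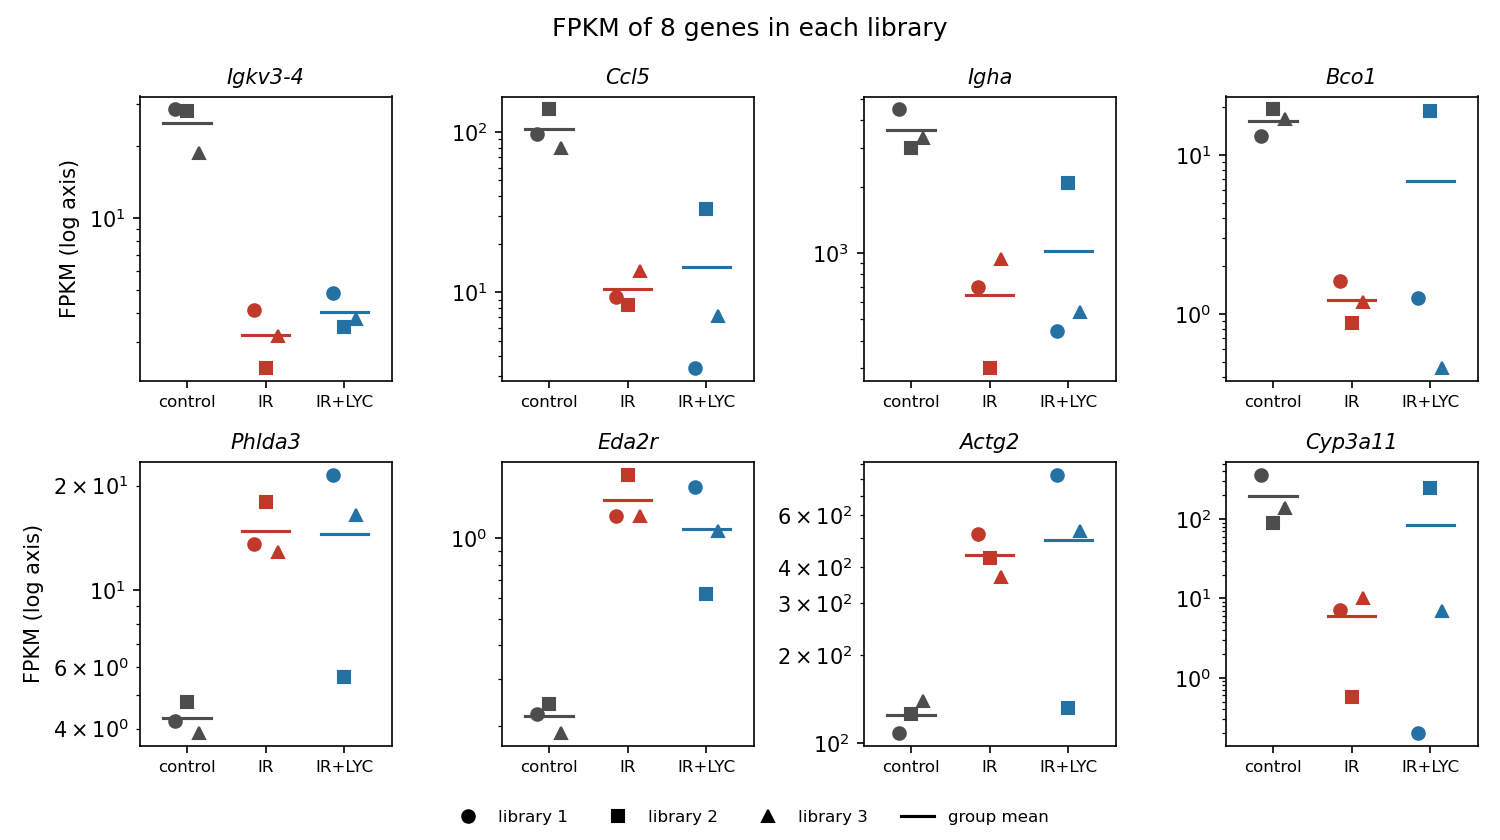
FPKM of 8 genes in each of the 9 libraries, on a log axis, with lines at the group means.

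Weaker sets in IR against control followed, with 0 members past either threshold. Intestinal lipid uptake genes were lower in 18 of 20 members (median log2 -0.88, -0.31 without IR 2, adjusted p = 0.00964; adjusted p = 0.692 with an estimated correlation), a call that ended without control 1 (0.0693) or IR 2 (0.294). Crypt stem cell genes were higher in 13 of 16 (median log2 0.26, adjusted p = 0.0195; adjusted p = 0.692 with an estimated correlation), a call that ended without IR 1 (0.0605) or IR 2 (0.0545), and after rescaling (0.142). Mitochondrially encoded genes were lower in 12 of 13 (median log2 -0.37, -0.17 without control 1 and -0.20 without IR 2, adjusted p = 0.0309; adjusted p = 0.692 with an estimated correlation), a call that ended without control 1 (0.391) or IR 2 (0.262). ER stress genes were lower in 13 of 15 (median log2 -0.14, -0.21 without control 1 and -0.22 without IR 1, and 0.09 after rescaling; adjusted p = 0.0330; adjusted p = 0.692 with an estimated correlation), a call that ended without control 2 (0.156) or IR 3 (0.143), and after rescaling (0.0668). MHC class II genes were lower in 10 of 11 (median log2 -0.26, -0.11 without IR 1 and -0.40 without IR 2, adjusted p = 0.0494; adjusted p = 0.692 with an estimated correlation). That call ended without control 2 (0.1300), control 3 (0.0594), IR 1 (0.717), IR 3 (0.0619), IR+LYC 1 (0.0626) or IR+LYC 2 (0.146), and with a pseudocount of 0.1 (0.0672), a mean of at least 5 FPKM (0.117), median-ratio scaling (0.0560), rescaling (0.1095), the fit of the 2 groups (0.116) or limma-voom (0.0754). It was kept in 6 of 18 alternatives.

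Without IR+LYC 2, 6 members of the T cell list, 4 of the B and plasma cell, 3 of the tuft cell, 2 of the smooth muscle, 2 of the p53 target, 1 of the xenobiotic and 1 of the matrix list passed over all genes tested, and 0 of the other 13 lists called. In all, 20 of the 37 lists passed in IR against control, 9 higher and 11 lower. After rescaling without mitochondrial, immunoglobulin and pancreatic genes the split was 4 higher and 10 lower. The calls on interferon response (median 0.69, adjusted p = 0.0862), p53 target (0.27, 0.0519), regenerative (0.70, 0.0876) and neutrophil genes (0.67, 0.1095) ended there, although their medians were larger. That rescaling moved the median of all genes by 0.17 log2 in IR against control and in IR+LYC against control, so these directions are relative to the deposited scale. With a correlation between members estimated from the data 0 of the 37 passed, the smallest adjusted p being 0.426, and with fry 0 passed (smallest 0.135).

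In IR+LYC against IR no gene passed, and 16 of 37 lists did with a preset correlation, interferon response genes with the smallest p. With an estimated correlation 0 passed (adjusted p = 0.599 for that list). Cxcl9 (chromosome 5, 92321347 to 92328079), a chemokine that interferon gamma induces, was at 18.9 ± 12.3 FPKM in IR and 6.08 ± 1.33 in IR+LYC (SD, n = 3). Loxl2 was at 6.90 ± 0.900 and 4.78 ± 0.977 FPKM. With limma 0 of 15391 genes passed (smallest adjusted p 0.489; 655 with an unadjusted p under 0.05), and with limma-voom 0 (746 unadjusted). Groups did not overlap at 1147 genes, 7.45% where the splits average about 10%.

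Interferon response genes were lower in IR+LYC in 24 of 24 members (median log2 -0.72, -1.34 without IR 1 and -0.28 without IR 2, camera adjusted p = 7.18e-09; adjusted p = 0.599 with an estimated correlation). Of these, 0 passed adjusted over the list alone and 0 over all genes tested. Irf7, the master factor of the type I response, was at 49.4 ± 32.7 and 18.5 ± 9.59 FPKM, and Ifit1, which binds viral RNA, at 32.7 ± 19.5 and 11.7 ± 9.45. Gbp2, a guanylate binding protein, was at 42.2 ± 28.6 and 19.2 ± 2.54. IR 1 (score -0.712) lay below all 3 IR+LYC libraries (-0.686, 0.00629 and -0.438), so the difference rests on IR 2 and IR 3. Mitochondrially encoded genes were higher in 13 of 13 members (median log2 0.45, 0.19 without IR+LYC 2, adjusted p = 1.65e-05; adjusted p = 0.599 with an estimated correlation, with 0 members past either threshold), with the cytochrome b gene mt-Cytb at 4728 ± 712 and 6554 ± 1637 FPKM. Without IR+LYC 2 this call ended (adjusted p = 0.161). Extracellular matrix genes were lower in 20 of 20 members (median log2 -0.39, -0.69 without IR+LYC 1 and -0.04 without IR+LYC 2, adjusted p = 2.54e-05; adjusted p = 0.599 with an estimated correlation, with 0 members past either threshold). The collagen Col6a1 was at 60.6 ± 3.85 and 41.3 ± 17.1 FPKM, and this call also ended without IR+LYC 2 (adjusted p = 0.433).

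Ileal genes were lower in 8 of 8 members (median log2 -1.11, -0.53 without IR+LYC 1, adjusted p = 0.000207; adjusted p = 0.599 with an estimated correlation, with 0 members past either threshold). The bile acid transporter genes Slc10a2 and Slc51a were at 10.1 ± 4.49 and 68.1 ± 9.78 FPKM in IR and 1.55 ± 0.359 and 35.0 ± 20.3 in IR+LYC, and since Fabp6 varied within groups, a difference in segment is open here. Tuft cell genes were higher in 9 of 10 members (median log2 0.25, 0.15 without IR+LYC 2, adjusted p = 0.000426; adjusted p = 0.599 with an estimated correlation, with 0 members past either threshold), Avil being at 0.776 ± 0.130 and 1.73 ± 0.640 FPKM. Enterocyte brush border genes were lower in 20 of 20 members (median log2 -0.75, -0.49 without IR 1, -1.60 without IR 2, -0.44 without IR 3, 0.07 without IR+LYC 1 and -1.78 without IR+LYC 2, adjusted p = 0.00137; adjusted p = 0.737 with an estimated correlation, with 0 members past either threshold). Naaladl1, a brush border peptidase, was at 497 ± 235 and 189 ± 98.1 FPKM. The call was lost without IR 1 (adjusted p = 0.0731), IR 3 (0.0797) or IR+LYC 1 (0.968). T and intraepithelial lymphocyte genes were lower in 18 of 19 members (median log2 -0.27, -0.42 without IR 1, -0.03 without IR+LYC 1 and -0.44 without IR+LYC 2, adjusted p = 0.00330; adjusted p = 0.730 with an estimated correlation, with 0 members past either threshold). The set did not pass without IR+LYC 1 (adjusted p = 0.887) or at a mean of at least 5 FPKM (0.192).

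Other sets in IR+LYC against IR had 0 members past either threshold. MHC class II genes were lower in 9 of 11 members (median log2 -0.27, -0.45 without IR 1, -0.08 without IR 2 and -0.41 without IR+LYC 3, adjusted p = 0.00223; adjusted p = 0.599 with an estimated correlation), a call that ended without IR 2 (0.226), IR+LYC 1 (0.0741) or IR+LYC 2 (0.146). Enteric neuron and glia genes were higher in 13 of 13 (median log2 0.26, 0.16 without IR 3, 0.10 without IR+LYC 1, 0.51 without IR+LYC 2 and 0.14 without IR+LYC 3, adjusted p = 0.00469; adjusted p = 0.730 with an estimated correlation), a call that ended without IR 3 (0.0939), IR+LYC 1 (0.492) or IR+LYC 3 (0.296). Crypt stem cell genes were higher in 13 of 16 (median log2 0.19, 0.13 without IR 3, -0.03 without IR+LYC 1, 0.47 without IR+LYC 2 and 0.11 without IR+LYC 3, adjusted p = 0.0175; adjusted p = 0.737 with an estimated correlation). That call ended without IR 3 (0.1255) or IR+LYC 3 (0.149), and without IR+LYC 1 it changed direction (0.518). Antioxidant genes were lower in 17 of 22 (median log2 -0.17, -0.26 without IR 2, -0.09 without IR 3, -0.04 without IR+LYC 1 and -0.30 without IR+LYC 2, adjusted p = 0.0197; adjusted p = 0.599 with an estimated correlation), with glutathione reductase (Gsr) at 129.8 ± 10.2 FPKM in IR and 91.4 ± 7.59 in IR+LYC. The call was lost without IR 3 (0.123), IR+LYC 1 (0.311) or IR+LYC 3 (0.163), and at a mean of at least 5 FPKM (0.0961). NF-kB targets were lower in 14 of 16 (median log2 -0.17, -0.26 without IR 1, -0.11 without IR 3, -0.30 without IR+LYC 1 and -0.06 without IR+LYC 3, adjusted p = 0.0197; adjusted p = 0.599 with an estimated correlation), a call that ended without IR 2 (0.0938), IR 3 (0.0970), IR+LYC 2 (0.124) or IR+LYC 3 (0.163), and with limma-voom (0.0555). Epithelial antimicrobial genes were lower in 11 of 15 (median log2 -0.56, -0.31 without IR+LYC 1, adjusted p = 0.0236; adjusted p = 0.599 with an estimated correlation), a call that ended without IR 1 (0.151) or IR+LYC 1 (0.446), and at a mean of at least 5 FPKM (0.121).

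Among named genes whose 2 groups did not overlap and whose higher group had a mean of at least 5 FPKM, the 5 with the smallest p in each direction did not pass, each with an adjusted p of 0.994. On the higher side the folate carrier Slc19a1 was at 4.65 ± 0.332 FPKM in IR and 7.74 ± 0.917 in IR+LYC, and Mcrip2, of stress granules, at 14.6 ± 1.35 and 27.0 ± 4.69. The noncoding RNA Gas5 was at 12.8 ± 1.501 and 19.1 ± 1.04, Ano7, of the anoctamin family, at 3.30 ± 0.338 and 5.55 ± 0.796, and Rgcc, a regulator of the cell cycle, at 7.81 ± 0.589 and 11.7 ± 1.70. On the lower side Fam102b was at 11.4 ± 1.85 and 6.44 ± 0.821, and the thrombin receptor F2r at 14.5 ± 1.21 and 9.36 ± 1.22. The collagen Col6a4 was at 8.66 ± 1.73 and 4.82 ± 0.852, Naaa, which hydrolyses acylethanolamides, at 16.4 ± 1.47 and 11.9 ± 0.444, and the prolyl hydroxylase Egln3 at 29.2 ± 7.32 and 15.5 ± 1.74. Of the 16 lists that passed, 6 were higher and 10 lower. With an estimated correlation the smallest adjusted p was 0.429, and with fry 0 passed (smallest 0.577).

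Against control, the same 3 genes passed as lower in IR+LYC as in irradiation without lycopene. Both comparisons use the same 3 controls and 1 estimate of the spread, so this overlap is not independent evidence. Lymphocyte, plasma cell and enterocyte lists were lower with the preset correlation and did not pass with an estimated one (adjusted p = 0.663 for each). Igkv3-4 fell from 25.2 ± 5.59 to 4.02 ± 0.707 FPKM (SD, n = 3), by 2.37 on the log2 scale (standard error 0.21, limma adjusted p = 0.0238, lower in 3 of 3). Trdc was at 2.85 ± 0.267 FPKM in control and 0.523 ± 0.474 in IR+LYC, and the peptide transporter Slc15a1 at 166 ± 11.4 and 47.3 ± 63.6. Igkv3-9 had 0 reads in each of the 3 IR+LYC libraries (adjusted p = 0.0238), as did Mir7061 (adjusted p = 0.0239).

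Over the alternatives the adjusted p ran from 0.00949 to 0.144 for Igkv3-4, 0.00880 to 0.122 for Igkv3-9 and 0.000117 to 0.249 for Mir7061. The count of 3 became 4120 without IR+LYC 2 (1731 higher, 2389 lower). It was 3 without IR 2, of which 2 were shared with the fit of all 9 libraries. It was 1 without control 2 (shared) or IR+LYC 3 (not shared), and 0 without control 1, control 3, IR 1, IR 3 or IR+LYC 1. With limma 2176 genes had an unadjusted p under 0.05 (1016 higher, 1160 lower), and limma-voom passed 0 genes, with 2357 unadjusted. The groups did not overlap at 2695 genes, 17.5% where the splits average about 10%, which again shows no excess over chance.

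T and intraepithelial lymphocyte genes were lower in 19 of 19 members (median log2 -1.19, camera adjusted p = 4.93e-13; adjusted p = 0.663 with an estimated correlation). Of these, 16 were past the threshold adjusted over the list alone and 0 over all genes tested. Cd3e, of the T cell receptor complex, was at 2.69 ± 0.545 FPKM in control and 0.909 ± 0.350 in IR+LYC, and Cd160 at 3.66 ± 1.09 and 0.975 ± 0.403. B and plasma cell genes were lower in 18 of 18 members (median log2 -1.15, -0.74 without control 2 and -0.70 without IR+LYC 1, adjusted p = 3.81e-06; adjusted p = 0.663 with an estimated correlation; 5 past the threshold adjusted over the list alone, 0 over all). Igha was at 3604 ± 780.2 and 1022 ± 920.3 FPKM, with 442, 2084 and 541 in the 3 IR+LYC libraries, IR+LYC 2 holding the most. Enterocyte brush border genes were lower in 20 of 20 members (median log2 -2.07, -1.18 without IR+LYC 1, adjusted p = 6.96e-07; adjusted p = 0.663 with an estimated correlation, with 0 members past either threshold). Xpnpep2, an aminopeptidase, was at 106 ± 27.7 and 19.8 ± 13.04 FPKM. Xenobiotic metabolism genes were lower in 22 of 23 members (median log2 -1.26, -0.62 without IR+LYC 1, adjusted p = 2.10e-05; adjusted p = 0.663 with an estimated correlation; 1 past the threshold adjusted over the list alone, 0 over all). The efflux pump Abcb1a was at 127 ± 17.5 and 52.5 ± 33.1 FPKM. Paneth cell genes were lower in 15 of 16 members (median log2 -0.82, -0.47 without IR+LYC 2, adjusted p = 4.45e-05; adjusted p = 0.663 with an estimated correlation; 1 past the threshold adjusted over the list alone, 0 over all). The set did not pass without IR+LYC 2 (adjusted p = 0.1201). Their score was lowest in IR+LYC 2 (-1.07), the library with the enterocyte level of a control.

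Smooth muscle genes were higher in 12 of 12 members (median log2 0.74, 0.27 without IR+LYC 1 and 1.42 without IR+LYC 2, adjusted p = 0.000143; adjusted p = 0.663 with an estimated correlation, with 0 members past either threshold). Actg2 was at 825, 132 and 529 FPKM in the 3 IR+LYC libraries against 124 ± 15.3 in control. Cell cycle genes were higher in 24 of 24 members (median log2 0.34, 0.55 without IR+LYC 2, adjusted p = 1.54e-06; adjusted p = 0.663 with an estimated correlation, with 0 members past either threshold). Ube2c, which drives exit from mitosis, was at 20.7 ± 2.64 and 29.6 ± 5.36 FPKM. Crypt stem cell genes were higher in 14 of 16 members (median log2 0.48, 0.19 without IR+LYC 1 and 0.80 without IR+LYC 2, adjusted p = 0.000408; adjusted p = 0.663 with an estimated correlation; 1 past the threshold adjusted over the list alone, 0 over all). That call ended without IR+LYC 1 (adjusted p = 0.0506). Prom1, a surface marker of crypt cells, was at 9.54 ± 0.666 and 16.9 ± 2.52 FPKM. Targets of p53 did not pass as a set (median log2 0.08, adjusted p = 0.0978), while 4 of 23 were higher adjusted over the list alone and 0 over all genes tested. Eda2r was at 0.218 ± 0.0268 and 1.08 ± 0.466 FPKM and Phlda3 at 21.5, 5.64 and 16.5 in the 3 IR+LYC libraries.

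Further sets passed in IR+LYC against control, with 0 members over all genes tested. MHC class II genes were lower in 11 of 11 members (median log2 -0.56, -0.37 without control 2, adjusted p = 0.000312; adjusted p = 0.663 with an estimated correlation), a call that ended without IR+LYC 2 (0.0505). Intestinal lipid uptake genes were lower in 18 of 20 (median log2 -1.45, -0.64 without IR+LYC 1 and -2.35 without IR+LYC 2, adjusted p = 0.000614; adjusted p = 0.663 with an estimated correlation; 1 passed adjusted over the list alone). Circadian clock genes were lower in 12 of 14 (median log2 -0.52, -0.86 without IR+LYC 2, adjusted p = 0.00333; adjusted p = 0.663 with an estimated correlation). Macrophage and monocyte genes were higher in 13 of 16 (median log2 0.39, 0.23 without IR+LYC 1 and 0.62 without IR+LYC 2, adjusted p = 0.0138; adjusted p = 0.663 with an estimated correlation; 1 adjusted over the list alone), a call that ended without IR+LYC 1 (0.198) and after rescaling (0.0618). Goblet cell genes were higher in 13 of 15 (median log2 0.35, 0.18 without control 1, 0.20 without IR+LYC 1 and 0.62 without IR+LYC 2, adjusted p = 0.0184; adjusted p = 0.663 with an estimated correlation), a call that ended without control 1 (0.196) and after rescaling (0.0522). Adipocyte genes were higher in 6 of 8 (median log2 0.86, adjusted p = 0.0211; adjusted p = 0.663 with an estimated correlation; 1 adjusted over the list alone), with the adipsin gene Cfd at 48.3 ± 4.08 and 149 ± 23.1 FPKM. The call was lost without IR+LYC 2 (0.438), without the filter (0.0656), at a mean of at least 5 FPKM (0.103) and after rescaling (0.1195). Enteric neuron and glia genes were higher in 11 of 13 (median log2 0.28, 0.11 without IR+LYC 1, 0.56 without IR+LYC 2 and 0.15 without IR+LYC 3, adjusted p = 0.0261; adjusted p = 0.668 with an estimated correlation), a call that ended without control 1 (0.0676), IR+LYC 1 (0.286) or IR+LYC 3 (0.253), and after rescaling (0.102). Ileal genes were lower in 6 of 8 (median log2 -1.46, -0.78 without IR+LYC 1, adjusted p = 0.0297; adjusted p = 0.663 with an estimated correlation), a call that ended without control 2 (0.0644), control 3 (0.0794), IR+LYC 1 (0.0636) or IR+LYC 2 (0.123). ER stress genes were lower in 13 of 15 (median log2 -0.30, -0.18 without IR+LYC 1, -0.48 without IR+LYC 2 and -0.16 without IR+LYC 3, adjusted p = 0.0488; adjusted p = 0.668 with an estimated correlation). The set did not pass without control 2 (0.137), IR 2 (0.0620), IR 3 (0.0507), IR+LYC 1 (0.222) or IR+LYC 3 (0.281), and with a pseudocount of 0.1 (0.0619), a mean of at least 5 FPKM (0.0886), rescaling (median -0.07, adjusted p = 0.128), the fit of the 2 groups (0.0578) or limma-voom (0.0547). It was kept in 8 of 18 alternatives.

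Without IR+LYC 2, where 4120 of 15391 genes (26.8%) passed, the share of members that passed was above this in 13 of the 17 lists called in the main fit and in 11 of the 20 others. Among the 17 it was 17 of 20 in the enterocyte list, 17 of 23 in the xenobiotic, 14 of 19 in the T cell, 14 of 20 in the lipid uptake, 13 of 16 in the crypt stem cell, 11 of 24 in the cell cycle, 10 of 12 in the smooth muscle, 9 of 14 in the circadian, 9 of 13 in the neuron and glia, 8 of 15 in the ER stress, 7 of 18 in the B and plasma cell, 7 of 16 in the macrophage (1 lower), 4 of 8 in the ileal, 4 of 15 in the goblet cell, 1 of 16 in the Paneth cell and 0 of 11 in the MHC class II list. In the adipocyte list, called higher, 2 of 8 passed and both were lower. The enterocyte median was then -2.92. In all, 17 of 37 lists passed, 7 higher and 10 lower, against 3 higher and 12 lower after the rescaling. With an estimated correlation 0 passed (smallest adjusted p 0.663), and with fry 0 (smallest 0.153).

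**Figure D3:**
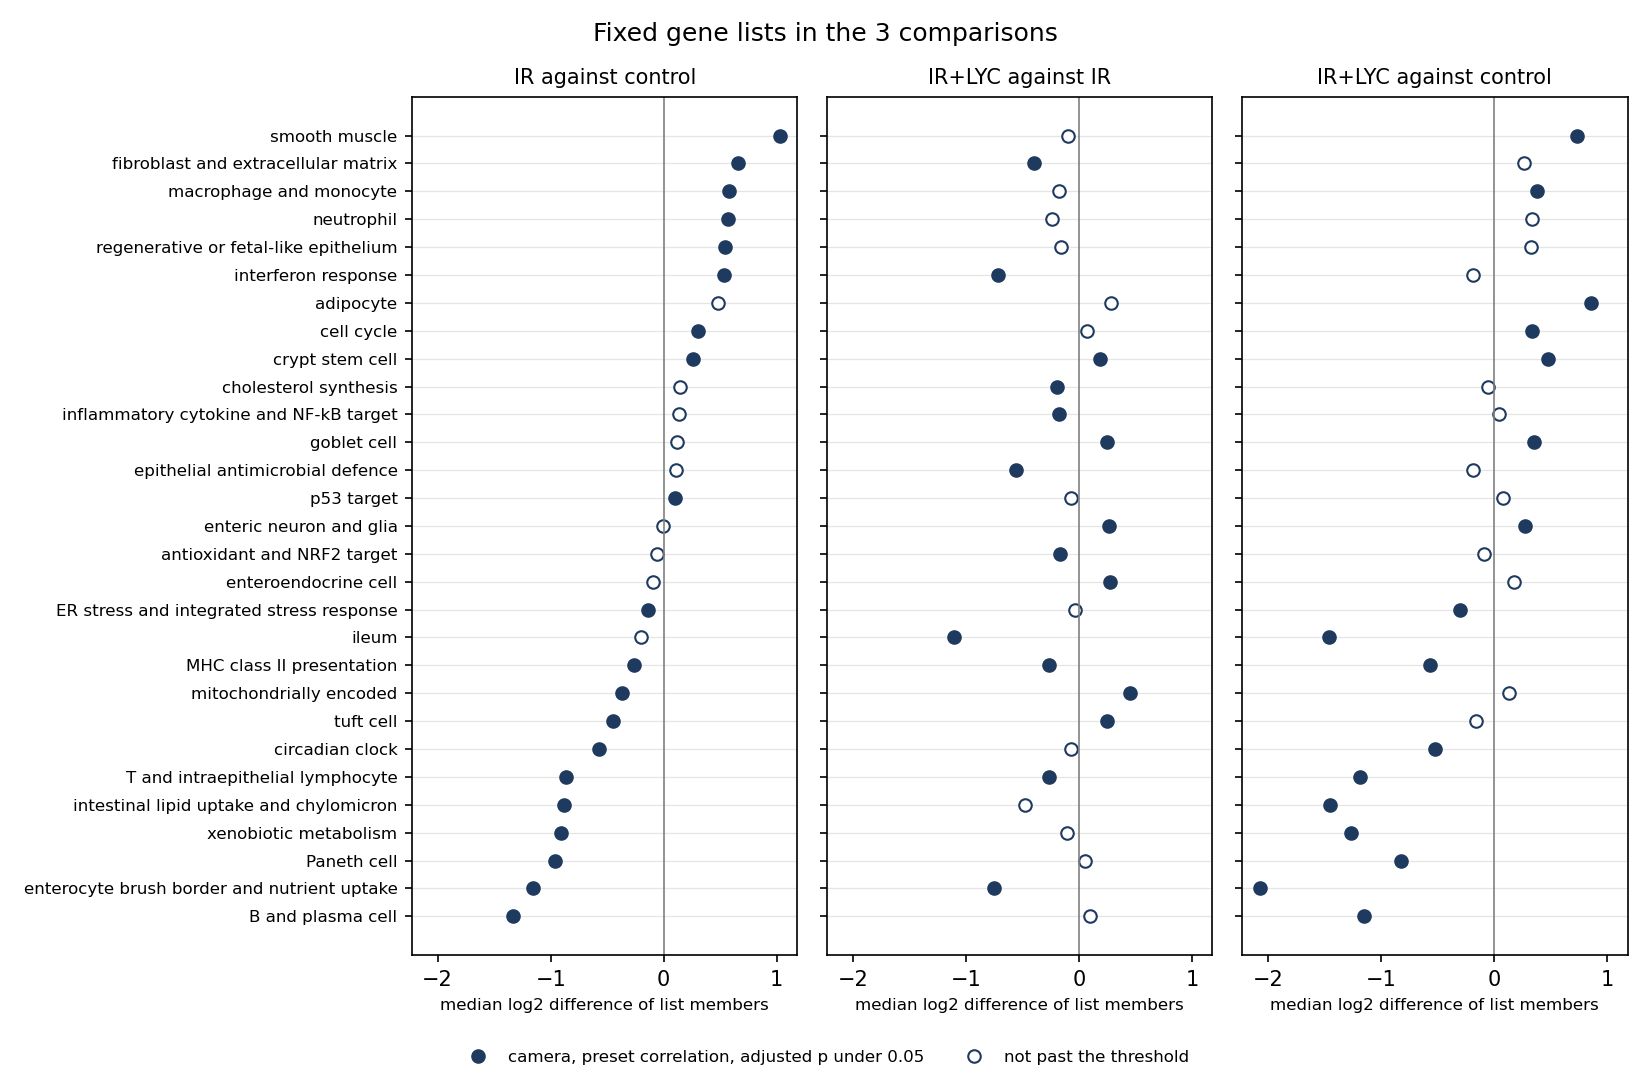
Median log2 difference of the members of each gene list that passed in any of the 3 comparisons; filled symbols passed camera with a preset correlation, and 0 lists passed with an estimated correlation.

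No gene changed in opposite directions in IR against control and IR+LYC against IR at the adjusted threshold (limma, 0 genes; limma-voom passed 0 in either). As no gene passed in IR+LYC against IR, this count could only be 0 and says nothing about a return towards control. At an unadjusted p under 0.05 in both, 129 genes were found, 120 of opposite sign and 9 of the same sign. Because the IR libraries enter both comparisons, opposite signs arise without any treatment effect. Simulated data without differences gave a mean of 229 and a median of 12 such genes in 100 fits. The simulation gave the 3 groups the same spread, while the real IR+LYC libraries differed more from one another. Its gene counts, and its correlations below, may thus differ from those of such groups without a treatment effect. The correlation between the 2 sets of log2 differences was -0.11, against a mean of -0.45 (-0.96 to 0.61) in simulated data, and leaving out IR+LYC 2 turned it to 0.36. It was -0.52 without IR+LYC 1, -0.24 without IR+LYC 3, -0.29 without IR 1, -0.06 without IR 2 and -0.33 without IR 3. On axes from control (0) to IR (1), each built without the IR library that was placed on it, the IR+LYC libraries lay at 1.06, 0.288 and 0.974 (mean 0.775 ± 0.424 SD), and the left-out IR libraries at 0.697, 1.10 and 0.701 (mean 0.833 ± 0.232). Each IR+LYC value is the mean over the 3 axes, which were built from 12, 73 and 15 genes. Left-out controls lay at 0.281, 0.393 and 0.923 on such axes, built from 10, 18 and 2 genes, which part the groups poorly. Axes of the 1741 to 3017 genes with an unadjusted p under 0.05, an alternative added after the data were seen, had left-out controls at 0.113 to 0.260 and left-out IR libraries at 0.566 to 1.31. On those that left out an IR library, IR+LYC 1 lay at 1.185 to 1.446 and IR+LYC 3 at 0.933 to 1.141. IR+LYC 2 lay at 0.1057 to 0.2593 there, about as low as the left-out controls. These tests did not show a return towards control with lycopene, and IR+LYC 2 alone lay below each left-out IR library.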

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

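Some of the alternatives were chosen after the data had been seen. For IR against control the count of 3 genes ran from 0 to 98 when 1 library was left out. It was 1 with a pseudocount of 0.1, 7 without the filter, 1 at a mean of 5 FPKM, 2 after rescaling, 2 at a log2 difference of 1, 4 without the trend, 0 with a block for the replicate number, 0 with limma-voom and 100 in the fit of the 2 groups (36 higher, 64 lower). Of the 100, 69 were also among the 98 found without IR+LYC 2, and 22 of the 64 lower ones were immunoglobulin or T cell receptor segments. Both of these fits leave out IR+LYC 2 by construction, which takes its spread out of the test. For IR+LYC against control the count of 3 ran from 0 to 4120 with 1 library left out (4120 without IR+LYC 2). It was 0 with a pseudocount of 0.1, 6 without the filter, 1 at a mean of 5 FPKM, 1 after rescaling, 2 at a log2 difference of 1, 1 in the fit of the 2 groups, 4 without the trend, 0 with the block and 0 with limma-voom. IR+LYC against IR gave 0 genes in every alternative run. No pairing by replicate number was seen: of 9 pairs with the same number 3 had a correlation over 0.1, and the 9 ran from -0.65 to 0.38. Pairs with different numbers ran from -0.61 to 0.64. With 3 libraries per group this cannot exclude a pairing.

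With 1 library left out 14 to 20 lists passed in IR against control, 13 to 24 in IR+LYC against IR and 13 to 18 in IR+LYC against control; with an estimated correlation and with fry the number was 0 in all 3. Outside those 2 tests, of 948 list calls over the alternatives 90 were lost, and the median changed sign in 5 of these. In IR against control these were interferon response genes without IR 2 (-0.0123), p53 targets at a mean of 5 FPKM (-0.149) and ER stress genes after rescaling (0.0936). That rescaling moved the median of all genes by 0.17, so the last of these says little about the list. In IR+LYC against IR they were crypt stem cell genes (-0.026, against 0.466 without IR+LYC 2) and enterocyte genes (0.0665), both without IR+LYC 1. Camera gave the opposite direction in 1 of the 5, the crypt stem cell genes (adjusted p = 0.518). At an unadjusted p in both comparisons, an added alternative, 120 genes had opposite signs instead of 0. The position of IR+LYC on the axis from control to IR was 0.740 to 1.02 over the alternatives, and the correlation of the 2 sets of differences -0.22 to -0.03, or -0.52 without IR+LYC 1 and 0.36 without IR+LYC 2. The cause of these shifts was not tested.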

Other observations

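Clock genes in IR against control, and hormone cell, goblet cell and cholesterol genes in IR+LYC against IR, were not described above. Circadian clock genes were lower in IR than in control in 11 of 14 members (median log2 -0.57, camera adjusted p = 0.00201; adjusted p = 0.578 with an estimated correlation; 0 members past either threshold). The transcription factor Hlf was at 4.15 ± 1.21 FPKM in control, 1.61 ± 0.0778 in IR and 2.41 ± 1.38 in IR+LYC (SD, n = 3), and the period gene Per2 was at 13.1 ± 1.09, 8.51 ± 0.803 and 8.98 ± 2.92. Enteroendocrine genes were higher in IR+LYC than in IR in 15 of 18 members (median log2 0.28, adjusted p = 0.000546; adjusted p = 0.429 with an estimated correlation). Somatostatin (Sst) was at 57.3 ± 6.02, 36.6 ± 2.54 and 52.3 ± 12.4 FPKM and cholecystokinin (Cck) at 9.33 ± 1.06, 10.5 ± 0.762 and 15.0 ± 4.60. Goblet cell genes were higher in IR+LYC than in IR in 12 of 15 members (median log2 0.25, 0.08 without IR+LYC 1, 0.40 without IR+LYC 2 and 0.15 without IR+LYC 3, adjusted p = 0.00630; adjusted p = 0.599 with an estimated correlation). Trefoil factor 3 (Tff3) was at 778 ± 121 and 1314 ± 449.7 FPKM, and the call ended without IR+LYC 1 (adjusted p = 0.162). Cholesterol synthesis genes were lower there in 21 of 22 members (median log2 -0.19, -0.13 without IR 1, -0.31 without IR 3 and -0.12 without IR+LYC 2, adjusted p = 0.00136; adjusted p = 0.599 with an estimated correlation), a call that ended without IR 1 (adjusted p = 0.0603). No member of these 4 lists passed over all genes tested.

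In this part the tests on IR+LYC 2, Bco1 and smooth muscle were chosen only after the results were seen, while the splits of the libraries were planned. Library IR+LYC 2 lay near the controls in enterocyte, muscle and xenobiotic genes. Were it a mislabelled control, its position on axes that leave out 1 control each should match that of a left-out control: it was 0.276 on average against 0.113 to 0.260 on axes of genes at an unadjusted p, and 0.232, 0.487 and 0.791 against 0.281, 0.393 and 0.923 on those of the 10, 18 and 2 genes at an adjusted p. Towards irradiation lay its p53 target score of 0.203 (controls -0.117 to -0.066, IR+LYC 3 at -0.138), Paneth score of -1.07 (0.338 to 0.664) and T cell score of 0.0292 (0.593 to 1.14), with Eda2r at 0.624 FPKM (0.189 to 0.242), Ccng1 at 34.0 (24.0 to 25.6), Igkv3-4 at 3.46 (18.7 to 28.6) and an immunoglobulin share of 0.938% (1.496 to 2.01%). The p53 target and Paneth scores lay beyond those of every IR library, not among them. Phlda3, another p53 target, lay nearer the control mean. It was at 5.64 FPKM in IR+LYC 2 against means of 4.28 in control and 14.8 in IR. Igkv3-4 was named from fits that held IR+LYC 2, so its value there is not independent of that choice. It also passed limma in IR against control without that library (adjusted p = 0.0118). Without IR+LYC 2, 98 genes were called in IR against control. In IR+LYC 2, 68 of them lay nearer the control mean and 30 nearer the IR mean. Bco1 lay 0.202 log2 above the control mean. Of 19 lists called without it, those of p53, Paneth and T cell genes lay beyond the controls towards IR by more than their range. Crypt stem cell, matrix and ER stress lists lay as far outside on the other side, and 13 lists did neither. With 3 controls, this library and an atypical unirradiated one thus cannot be told apart. A more proximal segment, or a weaker injury of that sample, which was not tested, may also explain it: its proximal minus ileal score was 1.997, above the other IR+LYC libraries by 2.36, a gap within the range of 3.22 that the other 8 libraries span.

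Bco1 was lower in IR than in control, at -2.73, -3.20 and -2.98 log2 against the control mean in IR 1, IR 2 and IR 3. A loss of enterocytes as the whole cause is unlikely in IR 1 and IR 3, where the median of 20 enterocyte genes was at -0.45 and -0.42, Bco1 lay below each of them, and its difference from their median was -2.42 (standard error 0.29). A more distal segment as the whole cause is unlikely there as well, since Bco1 lay below each of 7 proximal markers and differed from their median by -2.63 (standard error 0.31). Both standard errors come from the controls, IR 1 and IR 3. IR 2 was set apart after its values were seen, so they may be too small. In IR 2 Bco1 lay within the range of both lists (-0.64 and -1.70 from their medians), so in this 1 library either explanation and a change of the gene itself cannot be told apart. A loss of only some enterocytes, or less Bco1 in each, may explain the fall and was not tested.

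Smooth muscle genes were higher in IR, though as a list they did not pass with an estimated correlation (camera adjusted p = 0.578). More muscle wall in the tissue taken was weighed as the cause. Enteric neuron and glia genes of the same wall did not move with them: the medians with limma-voom were 1.04 for 12 muscle genes and -0.06 for 14 neuron and glia genes, a difference of 1.10 (permutation of list members, p = 0.0002 in 100000 resamples, which treats members as independent). Estimated correlations between members were 0.946 (muscle) and 0.867 (neuron and glia), so this p does not measure the spread between libraries. Muscle scores were 0.534, 0.388 and 0.157 in IR against -0.726, -0.661 and -0.465 in control. Neuron and glia scores were -0.0577, 0.0874 and -0.259 in IR against -0.189, -0.0167 and -0.0770 in control, and overlapped. More wall as the only cause should have raised both, unless irradiation itself lowered neuron and glia genes, which was not tested. If it did not, these scores argue against that cause in IR, with 3 libraries per group and no test between them. Within IR+LYC both lists moved together, so a varying amount of wall stays open there. Muscle scores there were 1.154, -0.845 and 0.4635, and neuron and glia scores 0.479, -0.414 and 0.448. A change in muscle cells themselves or in myofibroblasts, which share these genes, may explain the rise in IR and was not tested.

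Each comparison has 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. In IR against control 1 of 10 splits gave as many genes as the real 3, with 0 as the highest other. IR+LYC against control gave 1 of 10, with 2 as the highest other against the real 3, and IR+LYC against IR gave 10 of 10 with at least the real 0. In that last comparison the split of IR 1, IR 3 and IR+LYC 2 against IR 2, IR+LYC 1 and IR+LYC 3 called 3783 genes, which points to a structure of the samples that the groups do not follow. For lists, 1 of 10 splits gave as many as the real 20 in IR against control (highest other 18), 6 as many as 16 in IR+LYC against IR (highest other 27) and 4 as many as 17 in IR+LYC against control (highest other 20).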
